A study of Mus musculus with 2 samples.

How the data were processed

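Poly(A) RNA from the testes of BALB/c mice at postnatal day 45 was sequenced in 2 libraries, 1 from control animals and 1 from animals exposed to bisphenol A (BPA). Per the labels' protocols, RNA was extracted with Trizol, enriched with oligo(dT) beads, fragmented and copied into cDNA from random hexamers, and no step that marks the strand was described. Per the labels, the material of 3 samples was mixed before sequencing in each group, so each group has 1 library and the spread within a group was not measured. The control library was assigned from its title, which carries no treatment, and the BPA library from its treatment label. Dose, route and duration of exposure are not given in the sources used here.

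Per the submitters' processing notes, HISAT2 2.0.4 and HTSeq 0.6.1 were used with build mm10; the annotation, the strand setting, the scaling method and the program behind the p-values are not given in the sources used here. The authors deposited a table of 44002 rows with 1 value per library, a log2 fold change, a p-value and a q-value, together with lists of the genes called higher and lower. The 2 value columns are headed as read counts, but the deposited values are CPM, reads scaled to a common total per library: they sum to 995266 in the BPA library and 997834 in the control library. Deposited CPM values under 1 are written as 0, and 10618 rows carry no value. The deposited log2 fold change equals the log2 ratio of BPA CPM over control CPM in the 17978 genes with both values above 0, with a largest gap of 4.98e-05. The authors' q-values equal Benjamini-Hochberg adjusted p-values within 1.78e-05. All 28 genes in the authors' lists, and no others, have a deposited q-value under 0.005 and a deposited log2 fold change above 1 in size.

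All CPM values above 0 in the deposited table are whole multiples of 1 step per library, within 2.33e-10 of a step. The step, 0.0220 CPM in the BPA library and 0.0239 CPM in the control library, was taken as the value of 1 read. On that reading the full CPM scale stands for 45377700 reads in the BPA library and 41801900 in the control library. The fold changes in the deposited table also gave values written as 0 where the other library was at 1 CPM or more. These were 812 in the BPA library and 592 in the control library, and a listed 0 without a deposited fold change stayed at 0. All 1404 came out as whole reads within 0.01 read. The design fixed before the data were examined had assumed values listed without such a limit. The filled values were therefore used throughout, and taking the listed zeros as 0 became an added alternative. No count model was fitted.

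Genes at 1 CPM or more in the higher library were compared by the log2 ratio of BPA over control with a pseudocount of 0.1 CPM, and a gene was called higher or lower when the ratio reached 2-fold. Fold differences given beside a gene are ratios of CPM without the pseudocount, with an exact 95% binomial (Clopper-Pearson) interval of the reads. These intervals cover counting error only, because PCR copies are not independent molecules and samples were pooled. Whether the 3 samples are 3 animals is not given in the sources used here. No test was made between the conditions, and an exact binomial test of the reads, added after the data were seen, compares the libraries only. For 38 gene lists fixed before the data were examined, the median log2 ratio was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. A list stands apart here when its percentile is under 2.5 or above 97.5; lists with fewer than 5 members at the floor have no percentile. The percentile describes these 2 libraries and not the conditions. Genes named are the 10 largest fold changes per direction in the authors' lists and the 10 largest log2 ratios per direction under the size rule. Naming under the size rule left out Gm numbers, Rik and other clone symbols and numbered pseudogenes, but not LOC symbols. Up to 4 members per list with the largest log2 ratio in size are also named. The lists standing apart and the spliceosome and meiosis lists come first.

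Symbols and positions came from the RefSeq annotation of GRCm38, the build that mm10 names; 40269 of 41571 numeric gene IDs matched, and 2431 further rows are the authors' unnamed transcripts. Exon overlaps and 50-base words shared between genes at different loci were taken from GENCODE, through gene IDs and, for the rest, through symbols whose positions overlapped. Mitochondrially encoded genes were not analysed here, because no row matched that list. On simulated Poisson reads for 19389 genes at these depths, the size rule recovered 2% of 50 genes changed 1.5-fold, 44% of 50 changed 2-fold, 98% of 50 changed 3-fold and 100% of 50 changed 4-fold, and called 4 of 19189 unchanged genes. These draws hold counting error only and no other spread between libraries, so the shares need not hold for the real libraries. Alternatives covered the scaling, the floor, the pseudocount, the size rule, the counting interval, the mean in place of the median and unmatched random lists. Calculations ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.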

Results

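Testis transcripts of adolescent mice were compared between a control library and a library from mice exposed to BPA, a plastics monomer with estrogen-like activity. The series title names the spliceosome and meiosis as its subjects. Each group had 1 library, pooled from 3 samples, so no difference below has a replicate check. The listed values correspond to 45162887 reads in the BPA library and 41711330 in the control library. The 10 most abundant genes took 4.03% of the BPA library and 4.003% of the control library, the 100 most abundant took 15.3% of each, and cytosolic ribosomal protein genes took 1.44% and 1.40%. In the BPA library 18571 genes were listed above 0, against 18796 in the control library.

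The first comparison was that of the authors, whose deposited table calls genes higher or lower after BPA exposure. Haus1, a subunit of the augmin complex that builds the spindle, stood at 67.0 CPM in the BPA library and 2.11 CPM in the control library, 31.8-fold higher (95% counting interval 25.7 to 39.8). The vacuolar ATPase subunit gene Atp6v1c1 was 25.7-fold higher (19.3 to 35.0), and Zmynd15, a repressor required for spermatid maturation, was 14.1-fold higher (11.9 to 16.9). In the other direction Armc12, needed for the sperm mitochondrial sheath, stood at 3.15 CPM in the BPA library against 90.7 CPM in the control library, 28.8-fold lower (24.3 to 34.2). Snrpc, which encodes the U1 snRNP protein C, was 17.4-fold lower (15.1 to 20.2), and Hnrnpu, a nuclear RNA-binding protein, was 6.45-fold lower (5.91 to 7.05).

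The authors' deposited table calls 28 genes, 16 higher and 12 lower in the BPA library. The authors' deposited table gives Haus1 a log2 fold change of 4.99 with a q-value of 1.58e-13, Armc12 a log2 fold change of -4.85 with a q-value of 1.24e-18, and Snrpc a log2 fold change of -4.12 with a q-value of 2.73e-14. Further genes higher in the BPA library were Phtf1 (8.84-fold, 7.44 to 10.6), the bromodomain gene Brd2 (8.54-fold, 7.62 to 9.60), the chromatin remodelling gene Mta1 (7.91-fold, 6.72 to 9.35), Sumo2 (7.65-fold, 6.78 to 8.66), Tex22 (6.82-fold, 6.18 to 7.55), the proteasome subunit gene Psmb6 (6.56-fold, 6.11 to 7.04) and Nudt3 (6.53-fold, 5.73 to 7.48). Further genes lower in the BPA library were LOC100862220 (106-fold, 57.2 to 221, on 10 reads in the BPA library), Neurl4 (17.2-fold, 13.6 to 22.2), the adipocyte fatty acid carrier Fabp4 (11.8-fold, 9.55 to 14.7), Dgcr2 (11.6-fold, 9.63 to 14.2), Gps2 (9.45-fold, 8.67 to 10.3), Fam229a (9.28-fold, 8.12 to 10.7) and Gm10488 (7.85-fold, 6.78 to 9.13). On GRCm38, Haus1 (gene ID 225745) spans chromosome 18 from 77757277 to 77773885, Armc12 (67645) chromosome 17 from 28530861 to 28538975, and Snrpc (20630) chromosome 17 from 27840028 to 27851968. Gm10488 shared 100% of its 50-base words, and Sumo2 18.2%, with genes at other loci, so their reads are uncertain. Exons of Haus1, Zmynd15, Phtf1, Brd2, Nudt3, Dgcr2 and Hnrnpu overlap exons of another annotated gene. Reads from the overlapping parts cannot be assigned to 1 partner without strand. The span of Haus1 overlaps that of Atp5a1, which runs from 77773768 to 77782869. Atp5a1 went the other way, at 3.79 CPM in the BPA library against 25.3 CPM in the control library.

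The second comparison covered all 19389 genes at the floor of 1 CPM. Rapsn, which clusters acetylcholine receptors at the muscle synapse, was 31.5-fold higher in the BPA library (16.4 to 69.6), and Snrnp40, a component of the U5 snRNP, was 22.2-fold higher (15.0 to 34.3). Dgcr8, the partner of Drosha in microRNA processing, was 20.7-fold higher (11.1 to 43.8), and the vesicle fusion gene Vamp8 was 10.1-fold higher (6.88 to 15.3). Pitpnm1, a phosphatidylinositol transfer gene, was 40.1-fold lower (22.2 to 80.9), the RNA polymerase I subunit gene Znrd1 30.6-fold lower (20.8 to 46.7), Apip 25.7-fold lower (17.1 to 40.5) and the acetylcholine receptor subunit gene Chrne 17.4-fold lower (12.9 to 24.1). Low read numbers left wide intervals for Trem2, 61.7-fold higher (16.8 to 514.9, 2 reads in the control library), for Txnrd2, 85.7-fold higher (15.0 to 3420, 1 read in the control library), for Psmd10, 48.0-fold lower (18.4 to 178, 4 reads in the BPA library) and for Pgm1, 49.2-fold lower (16.5 to 242, 3 reads in the BPA library). Exons of Rapsn, Dgcr8, Txnrd2 and Pgm1 overlap exons of another annotated gene, so the source of their reads is uncertain. In all, 11 of 31 annotated genes named from the authors' lists or by the size rule had such an overlap. Gene list members named below can have it without being marked.

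By the size rule 256 genes were higher and 379 lower in the BPA library, and 18754 genes (96.7%) lay within 2-fold. These counts include genes with a mean under 1 CPM, which reached the floor only in the library where they were higher. The floor selects such genes for large ratios. With a mean from 1 to 4 CPM, 107 genes were higher and 172 lower. From 4 to 10 CPM these counts were 30 and 36, and from 10 to 100 CPM 28 and 37. At 4-fold, 55 genes were higher and 85 lower. Among 2401 genes with a mean of 100 CPM or more, 2 were 2-fold or more apart, both higher in the BPA library: Lrrc27 with 254 against 46.6 CPM and Prrc2a with 211 against 88.6 CPM, named after their values were seen. Exons of Lrrc27 overlap exons of another annotated gene. Across genes, which are not independent replicates, the log2 values of both libraries had a Pearson correlation of 0.984 and the CPM values a Spearman correlation of 0.985. The robust SD of the log2 ratio was 0.43 among genes with a mean from 1 to 4 CPM, 0.28 from 4 to 10 CPM, 0.15 from 10 to 100 CPM and 0.08 above. With a floor of 4 CPM the counts were 80 higher and 103 lower, and with 2-fold required of the nearer interval bound they were 100 and 162.

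**Figure D1:**
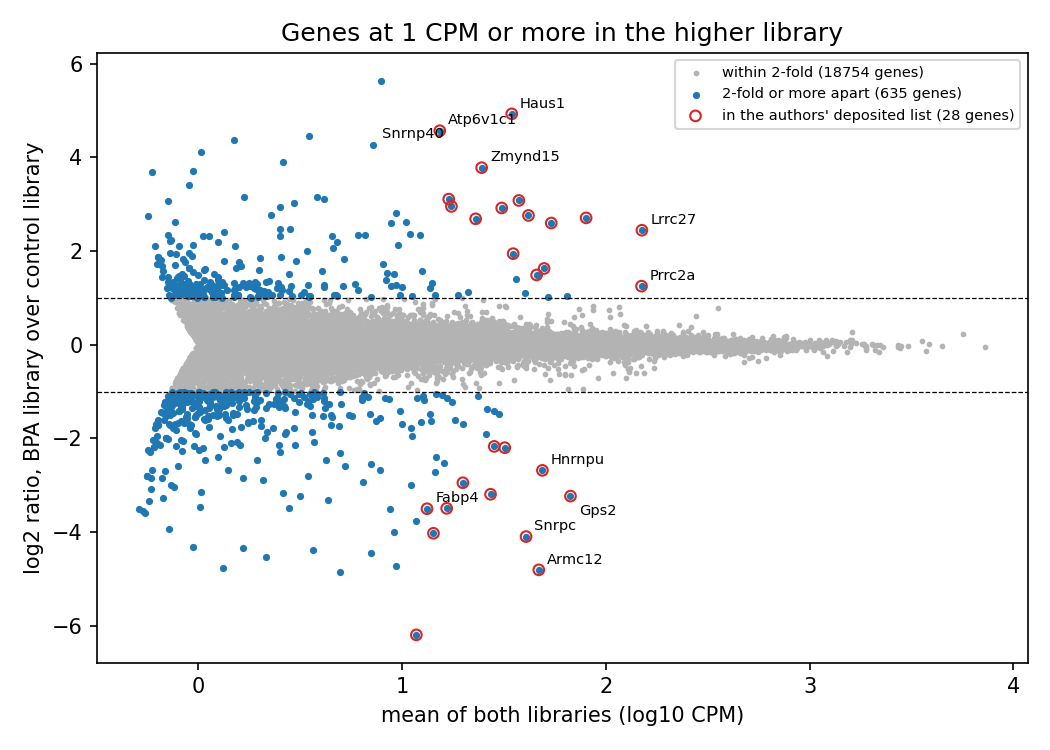
Log2 ratio of the BPA library over the control library (y axis) against the mean of both libraries in log10 CPM (x axis) for 19389 genes, with dashed lines at 2-fold. Blue points are the 635 genes 2-fold or more apart, and red rings mark the 28 genes of the authors' deposited list, from Haus1 at 4.93 down to LOC100862220 at -6.19.

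The genes of the spliceosome and of meiosis, which the series title names, were at nearly equal levels in both libraries, apart from a few members. Of 84 spliceosome core and snRNP genes at the floor, 2 were higher in the BPA library, Snrnp40 and the tri-snRNP factor Usp39 (2.52-fold, 2.22 to 2.87), and 1 was lower, Snrpc. Cwc22, which loads exon junction complexes, stood at 14.1 CPM against 26.6 CPM, and 17.4% of its words occur at other loci. The median log2 ratio of the list was -0.02, at percentile 8.32 of the matched random lists. Of 64 SR proteins, hnRNPs and exon junction factors, Srpk1, the kinase of SR proteins, was 2.07-fold higher (1.96 to 2.19) and Hnrnpu was lower, while Celf1 (log2 ratio 0.67) and Srsf1 (0.51) lay within 2-fold. That list had a median of 0.01 at percentile 73.7. Snrpc and Srpk1 lie in a stretch of chromosome 17, and Usp39 and Snrnp40 in shorter runs on chromosomes 6 and 4. In each of these, other genes within 1 Mb were also 2-fold or more apart, as described under the other observations. The cause of these clustered differences cannot be told with 1 library per group.

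Of 64 meiotic prophase genes, 1 was 2-fold apart: Majin, which ties telomeres to the nuclear envelope, at 2.42 CPM against 4.98 CPM, 2.05-fold lower (1.62 to 2.61). Mnd1 (log2 ratio -0.53), M1ap (-0.52) and Spata22 (0.47) lay within 2-fold, and the list's median was 0.02 at percentile 79.6. Of 61 genes of the meiotic divisions and cell cycle, the centriole duplication kinase Plk4 was 6.29-fold higher (5.19 to 7.69) and the centrosomal kinase Nek2 2.28-fold lower (2.005 to 2.594). Cdc16 (0.44) and Mybl2 (-0.34) lay within 2-fold, and the list's median was 0.01 at percentile 56.2. Hspa4l, within 1 Mb of Plk4 on chromosome 3, was also higher in the BPA library. Reads are uncertain for Mnd1 and Mybl2, which share 41.8% and 18.9% of their words with other loci, and for Nek2 and Spata22, whose exons overlap another gene.

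Germ cell stages were also alike. All 30 spermatogonial, 31 spermatocyte, 41 round spermatid and 45 elongating spermatid markers at the floor lay within 2-fold. The median log2 ratio was 0.01 for spermatogonia (percentile 49.2), -0.02 for spermatocytes (28.2), -0.01 for round spermatids (35.5) and 0.04 for elongating spermatids (99.9). In elongating spermatids 31 of 45 markers lay above 0; Prm1, a protamine of sperm chromatin, stood at 1762 CPM in the BPA library and 1463 CPM in the control library, and Tcp11 at 109 and 155 CPM. That list lost its place outside the random lists with the mean in place of the median (percentile 92.8) and with unmatched random lists (81.4). The largest log2 ratios elsewhere were those of Utf1 (-0.80), Lin28a (0.63), Egr4 (-0.44) and Stra8 (0.42) among spermatogonia, Pou5f2 (0.36) among spermatocytes and Tssk3 (0.70) among round spermatids.

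Among the somatic cells of the testis, Sertoli cell markers leaned toward the BPA library by less than 2-fold: 33 of 36 lay above 0 and their median log2 ratio was 0.19, above all random lists (percentile 100). By the 2-fold rule 0 were higher, 1 was lower and 35 lay within. Shbg stood at 9.19 CPM against 5.57 CPM, the follicle-stimulating hormone receptor Fshr at 3.64 against 2.25 CPM, and Hopx at 11.7 against 7.51 CPM. Rhox8, a homeobox gene of Sertoli cells, went the other way, 6.31-fold lower (4.84 to 8.35). Leydig cell and steroidogenic genes, 34 at the floor, all lay within 2-fold with a median of 0.06 (percentile 94.99); Hsd3b6, a steroid dehydrogenase of adult Leydig cells with 16.7% of its words at other loci, stood at 41.4 against 23.6 CPM and Star, which brings cholesterol into mitochondria, at 95.9 against 70.9 CPM. Blood-testis barrier genes had a median of 0.05 (percentile 91.2), with Tjp3 lower (1 of 25), Cdh2 at 46.6 against 71.5 CPM and the adhesion gene Jam2 at 18.1 against 12.6 CPM. Peritubular and smooth muscle markers had a median of 0.07 (percentile 85.2), macrophage and immune markers 0.10 (85.7) and endothelial markers -0.07 (18.3), all within 2-fold.

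Adipose tissue markers differed most of all lists. Of 9 at the floor, 7 were lower in the BPA library and none was higher, and the median log2 ratio was -2.89, below all random lists (percentile 0). Besides Fabp4, the lipid droplet gene Cidec was 13.9-fold lower (8.50 to 24.3), adipsin (Cfd) 11.3-fold lower (7.82 to 16.7) and Car3 8.23-fold lower (6.73 to 10.1). The markers summed to 27.4 CPM in the BPA library and 88.9 CPM in the control library. Of 44 cholesterol and lipid genes, 2 were lower, and both are also abundant in fat: lipoprotein lipase (Lpl), 6.61-fold lower (5.30 to 8.32), and the desaturase gene Scd1, 2.80-fold lower (2.57 to 3.06). The rest of that list lay within 2-fold, with Stard4 at 15.6 against 9.74 CPM and Dhcr7 at 28.9 against 20.6 CPM, and its median of 0.06 was above the random lists (percentile 98.9), but not with the mean over the list (54.6) or unmatched random lists (95.5).

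**Figure D2:**
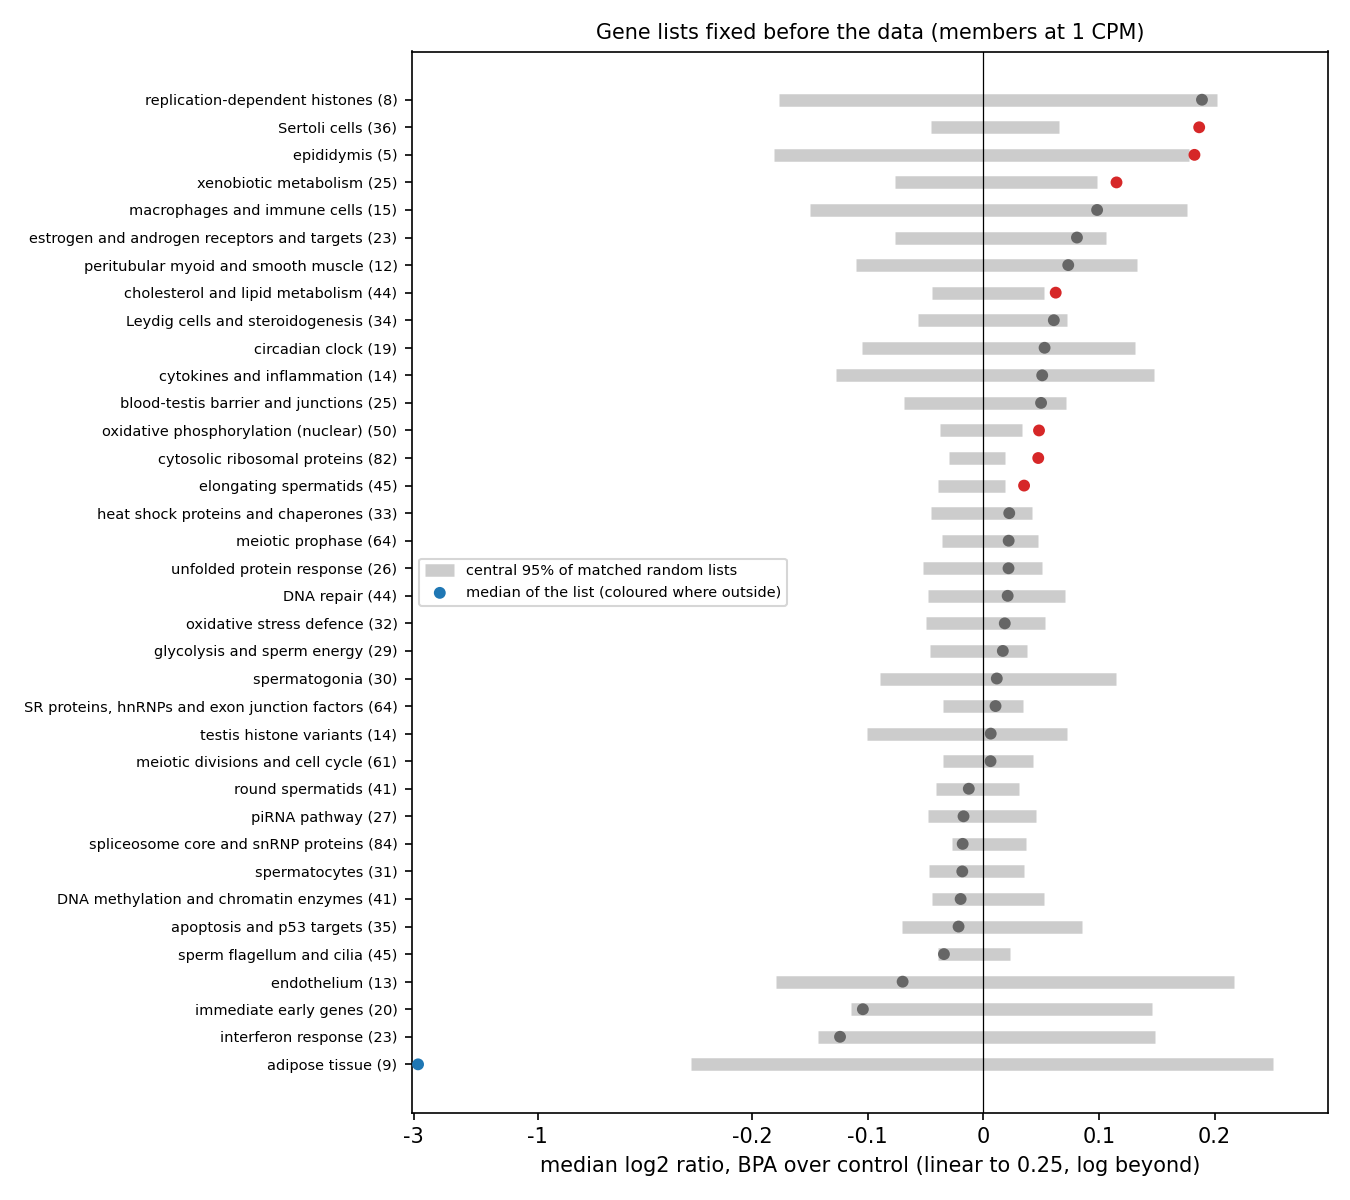
Median log2 ratio of BPA over control (x axis, linear to 0.25 and logarithmic beyond) for 36 gene lists (y axis, members at the floor in parentheses), with grey bars for the central 95% of matched random lists. Red and blue points lie outside their bars; Sertoli cells at 0.19 are farthest above theirs and adipose tissue at -2.89 farthest below.

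By their medians, other cells and pathways moved less than adipose tissue. Epididymal markers, 5 of 34 at the floor, had a median of 0.18 (percentile 97.8), led by Wfdc10 at a log2 ratio of 0.68. Among them Cst12, at 59.7 CPM in the BPA library against 51.1 CPM in the control library, is also in the Sertoli list. Of 4 red blood cell genes, Hba-a1, Hbb-bs and Alas2 lay within 2-fold, and Hbb-b1 had 0 reads in the BPA library; these globin genes share sequence, which leaves the source of their reads uncertain. Xenobiotic metabolism genes, 25 at the floor, had a median of 0.12 (percentile 98.9); Gstp1, a glutathione transferase that shares 36.3% of its words with other loci, was 4.79-fold higher (3.70 to 6.30) and Cyp2e1 was 2.36-fold lower (1.68 to 3.34). Cytosolic ribosomal protein genes (82, percentile 99.98) and nuclear genes of oxidative phosphorylation (50, percentile 99.6) each had a median of 0.05. Within them Rpl10a was 2.95-fold higher (2.49 to 3.51), Rps18 5.17-fold lower (4.01 to 6.76) and the ATP synthase subunit gene Atp5a1 6.67-fold lower (5.67 to 7.88). Exons of these 3 genes overlap another gene, and 19.4% of the words of Rpl10a and 17.6% of those of Rps18 occur at other loci, so their reads are uncertain. With the mean in place of the median the percentile was 87.7 for epididymis, 97.0 for xenobiotic metabolism, 81.6 for ribosomal proteins and 39.8 for oxidative phosphorylation, whose mean lay below 0. In all, 8 of 36 lists stood apart, and 2 of these, adipose tissue and Sertoli cells, did so under all 5 list alternatives. The 1.8 lists set by the limits alone would hold only for independent genes and separate lists, whereas markers of a cell type vary together and some lists share members such as Sult1e1 and Nqo1.

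The remaining lists did not stand apart. Estrogen and androgen receptors and targets had a median of 0.08 (percentile 93.0), with Krt19 lower and Fkbp5 at 5.75 against 8.59 CPM. Immediate early genes had a median of -0.10 (percentile 3.31), with Nr4a2 3.20-fold lower (1.93 to 5.54), and interferon response genes a median of -0.12 (4.57), with Ifi27l2a 2.21-fold lower (1.71 to 2.85) and H2-D1, with 15.1% of its words at other loci, 2.10-fold lower (1.63 to 2.73). In oxidative stress defence (median 0.02, percentile 73.7) only Txnrd2 was 2-fold apart, and in the heat shock list (0.02, 87.5) only Hspa4l, 6.09-fold higher (5.60 to 6.62). Chromatin enzymes (-0.02, 18.6) held Ehmt2, a histone methyltransferase, 2.82-fold higher (2.62 to 3.03), DNA repair (0.02, 61.8) held Rad51c, 2.32-fold lower (1.72 to 3.16), and sperm flagellum and cilia (-0.03, 5.16) held Dnah5, 2.82-fold lower (1.83 to 4.46). No member was 2-fold apart among the lists of the unfolded protein response (0.02, 81.0), circadian clock (0.05, 74.9), apoptosis and p53 targets (-0.02, 21.2), piRNA pathway (-0.02, 25.6), cytokines (0.05, 72.0), testis histone variants (0.01, 67.8), replication-dependent histones (0.19, 96.9) and glycolysis (0.02, 84.2).

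**Figure D3:**
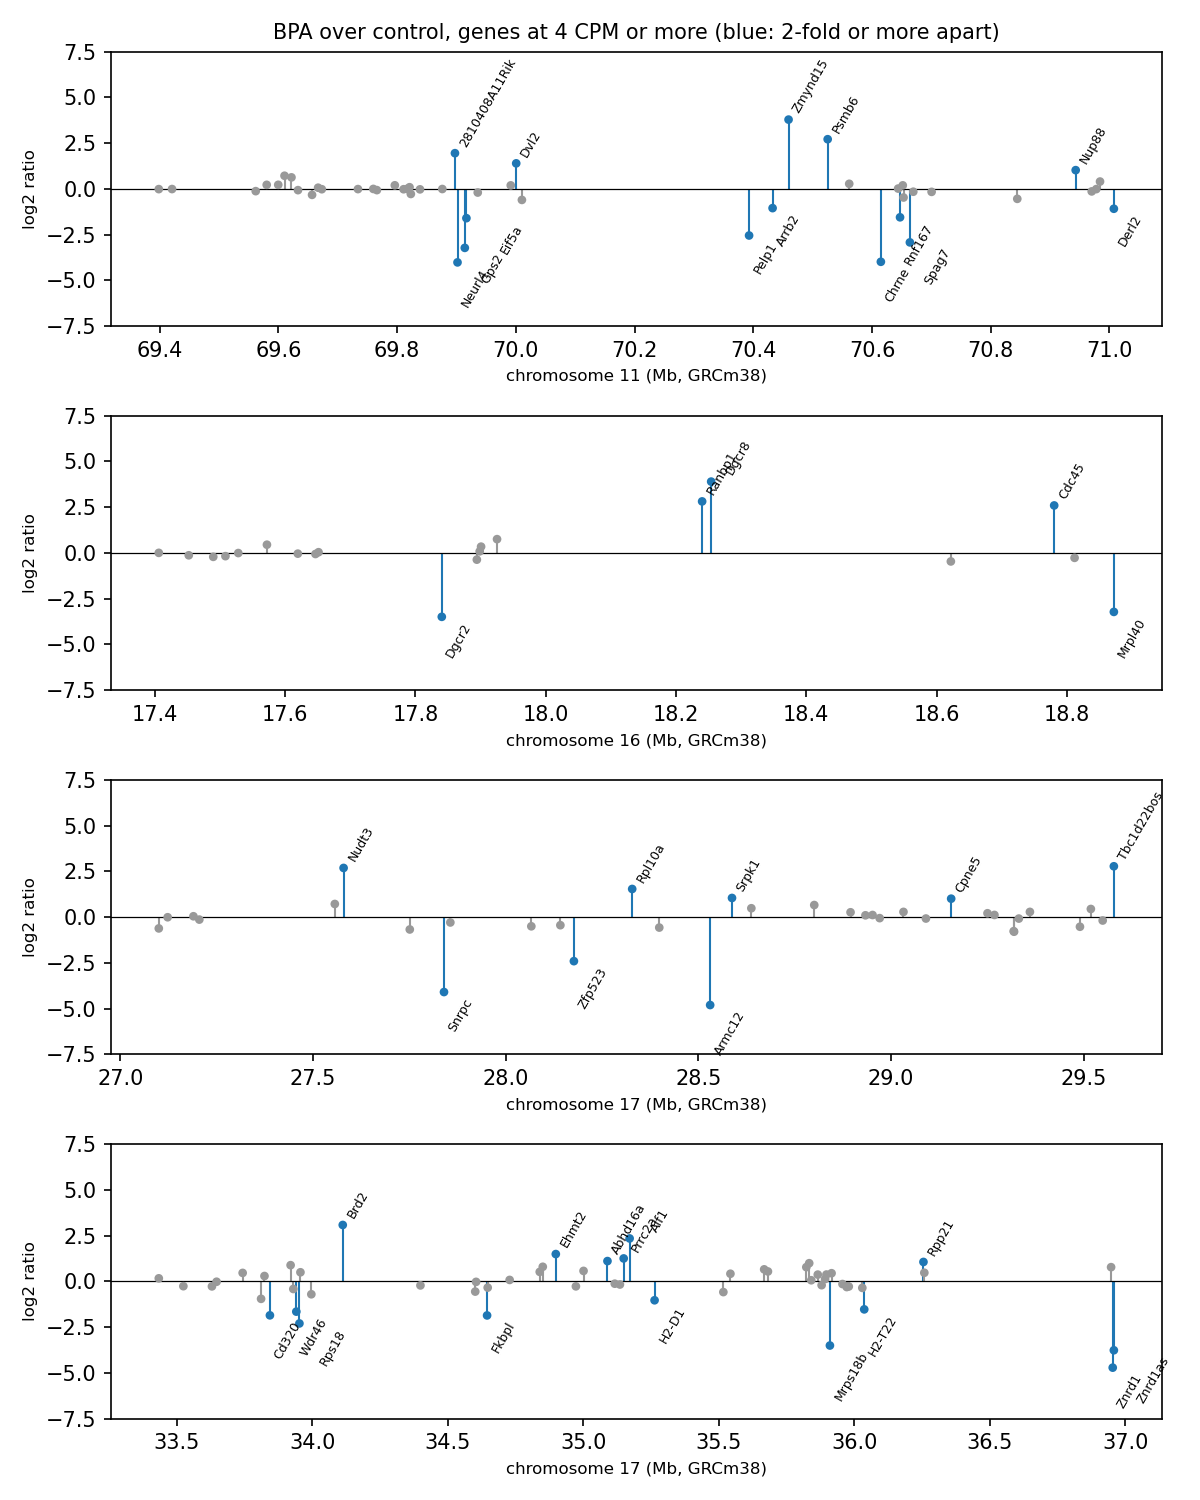
Log2 ratio of BPA over control (y axis) by gene start on GRCm38 (x axis, Mb) for genes at 4 CPM or more in 4 stretches of chromosomes 11, 16 and 17. Blue lines are genes 2-fold or more apart, and they point in both directions. Inside the stretches these are 42 of 115 genes, and genes flanking the stretches are also drawn.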

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

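Among these alternatives, taking listed zeros as 0 and the binomial test on reads were chosen after seeing the data, and the cause of each shift was not tested beyond what the setting itself changes. Scaling by the total, by the trimmed mean of log ratios or by the median ratio left 254 to 257 genes higher and 377 to 380 lower. The counts of 256 higher and 379 lower became 1938 and 2582 with no floor, where the authors' deposited table gives the fold changes. Those fold changes hold no pseudocount, so this setting dropped the floor and the pseudocount together. The main counts became 80 and 103 with a floor of 4 CPM, 82 and 123 with a pseudocount of 1 CPM, and 828 and 1042 at 1.5-fold. At 4-fold they were 55 and 85, on the nearer interval bound 100 and 162, and with listed zeros as 0 they were 686 and 937. A floor of 0.2 CPM was not run, because values under 1 CPM in both libraries are not listed. The authors' lists kept 16 and 12 genes at the floor and under the 2-fold rule, while an exact binomial test of the reads at the authors' thresholds, made over 19389 genes and not the 29279 of the authors' deposited table, compares the libraries and not the conditions and gave 271 and 394. Of the 8 lists standing apart, 2 did so under all 5 list alternatives, adipose tissue and Sertoli cells. With the mean over the list the percentile fell inside the limits for elongating spermatids (92.79), cholesterol and lipid metabolism (54.65), epididymis (87.73), xenobiotic metabolism (96.95) and ribosomal proteins (81.62), and for oxidative phosphorylation (39.76) the sign turned. With the mean it passed the limits for oxidative stress (99.58), heat shock (97.83) and sperm flagellum (1.05). With unmatched random lists it was 81.38 for elongating spermatids, 95.47 for cholesterol and lipid metabolism, 93.82 for epididymis, 95.41 for ribosomal proteins and 91.18 for oxidative phosphorylation, and it passed the limits for immediate early genes (1.94), interferon response (0.73) and replication-dependent histones (97.74). A floor of 4 CPM brought past the limits estrogen and androgen targets (97.97), interferon response (0.01) and testis histone variants (98.98), and left too few epididymis members. A pseudocount of 1 CPM did so for immediate early genes (2.49) and replication-dependent histones (98.03). Scaling by the total turned no median of a list standing apart, and no leave-one-out was possible with 1 library per group. Listed values start at 46 reads in the BPA library and 42 in the control library, where the limit of 1 CPM falls.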

Other observations

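Of 171 placed genes 2-fold or more apart at 4 CPM or more, 42 lay in 4 stretches, found by joining such genes within 1 Mb of each other into runs of at least 5, and 129 lay elsewhere. On chromosome 11 from 69897352 to 71019841, 14 of 27 genes were apart, with Zmynd15 and Psmb6 higher in the BPA library and Neurl4, Gps2, Chrne and Spag7 lower. On chromosome 16 from 17840355 to 18876637, 5 of 11 were apart, with Ranbp1, Dgcr8 and the replication factor gene Cdc45 higher and Dgcr2 and Mrpl40 lower. On chromosome 17 from 27579382 to 29596305, 8 of 29 were apart, with Nudt3, Rpl10a and Srpk1 higher and Snrpc and Armc12 lower, and from 33843091 to 36965830, a stretch that holds the major histocompatibility complex, 15 of 48 were apart, with Brd2, Ehmt2 and Prrc2a higher and Rps18, Mrps18b and Znrd1 lower. These stretches held 12 of the 28 genes in the authors' deposited table of called genes. Among shorter runs outside these stretches, Sftpb, Usp39, Rnf181 and Vamp8 on chromosome 6 were higher in the BPA library. So were Hspa4l and Plk4 on chromosome 3 and Tex22, Mta1 and Crip2 on chromosome 12. On chromosome 4 Bsdc1 and Fam229a were lower and Gm12966 and Snrnp40 higher, and on chromosome 18 Haus1 was higher and Atp5a1 lower. Some of the genes apart were also far below their list in both libraries. Rps18 stood at 1.61 and 8.32 CPM in the BPA and control libraries, and Rpl10a at 12.6 and 4.26 CPM. The ribosomal protein genes had a median of 162 CPM in the BPA library and 157 CPM in the control library. Atp5a1 stood at 3.79 and 25.3 CPM, where the oxidative phosphorylation genes had medians of 93.1 and 92.1 CPM. By kind of gene, 342 of 14539 protein-coding genes and 145 of 2775 long noncoding RNA genes at 1 CPM were 2-fold or more apart. These kinds were not matched on expression, which matters for such counts. With a mean from 1 to 4 CPM, 107 of 5358 genes were higher and 172 lower. From 10 to 100 CPM, 28 of 7578 were higher and 37 lower.

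The tests of read sampling, of scattering over the genome, of the set without copies and overlaps, of fat tissue, of lipid genes and of the p-values were chosen only after the result was seen. Those of exon overlap and of copies were set before, and matching by symbol was added to them after gene IDs alone had covered 77.8% of the genes apart.

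At 4 CPM or more, 183 genes were 2-fold or more apart, against at most 0 in 100 sets of Poisson draws, which argues against counting error alone but does not cover PCR copies or differences between pools, and 33 pairs of neighbouring genes were both apart, against at most 10 in 10000 shuffles, which argues against differences scattered independently over the genome. Of the pairs, 21 went in the same direction and 12 in opposite directions. Exons overlapping another gene were no more frequent among them (25.9%) than in matched random sets (median 32.7%). Words shared with another locus were more frequent (22.8% of 162 genes, against an upper limit of 14.2% in matched random sets). Reads shared with copies may therefore account for some of those 37 genes. Neighbours were also taken anew among the 7637 genes without copies and overlaps, so these pairs need not be among the 33. There 18 neighbouring pairs were both apart, against at most 6 in shuffles. For the rest BPA exposure, a genetic difference between the pools and reads that also map to alternate scaffolds cannot be told apart, because each group has 1 library and such scaffolds were not tested.

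The lower adipose markers could come from fat tissue attached to the testes of the control pool, which would bring all abundant fat transcripts. Of 7 markers with over 200 reads, 5 were 2-fold or more lower, including Fabp4, Car3 and Retn, but Adipoq stood at 15.4 and 17.2 CPM and Plin1 at 4.47 and 4.88 CPM in the BPA and control libraries. Whether the testis itself supplies those reads was not tested, so fat tissue and an effect of BPA on fat genes cannot be told apart. The 39 lipid genes left without Lpl, Scd1, Pparg, Cd36 and Lipe, which fat also holds, had a median log2 ratio of 0.0855. That set leaves out Lpl and Scd1, the 2 members that were 2-fold lower. The whole list of 44, with those members, had a median of 0.06, which argues against a general fall of lipid genes between these libraries.

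The p-values in the authors' deposited table may have been computed from CPM as if these were read counts. The comparison took the 1950 genes with both values listed above 0 and a p-value under 0.5 in the authors' deposited table. The z-score behind that p-value, divided by the z-score of a Poisson difference, had a median of 1.01 with CPM and 0.154 with reads. At the same thresholds an exact binomial test of the reads called 271 genes higher and 394 lower among 19389 genes, where the authors' deposited table covers 29279 genes with p-values. All 28 genes called in the authors' deposited table were among them, and the test compares the libraries and not the conditions.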
